A study of Mus musculus with 6 samples.

How the data were processed

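RNA from B16F10.9 mouse melanoma cells was sequenced as 6 libraries, 3 of untreated cells and 3 of cells given recombinant mouse IFN-gamma (50 µg/ml, 24 h), with an Illumina TruSeq RNA V2 kit, per the labels' protocols. That kit does not mark strand, so fragments of a gene and of an overlapping antisense gene cannot be told apart. Per the submitters' processing notes, TopHat2 2.0.11, Cufflinks 2.2.1 and Cuffdiff were used with the GRCm38 build. Parameters, annotation release and read filters are not given in the sources used here.

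The authors' deposited table gives FPKM values per the file headers, 1 for each group, with the 3 libraries of a group reduced to 1 value by the authors. It also gives the authors' test score, p-value and q-value, and a log2 ratio computed by the authors of IFN-gamma over untreated. The deposited log2 ratio runs far outside a usable range where a group stands at a vanishing FPKM, so the ratio was recomputed here from the FPKM values, without a pseudocount. A title line of the table speaks of infected against uninfected samples, while its sample cells name B16 and IFN. The sample cells were followed, and Irf1 stood higher under IFN. Some genes picked by the naming rule are not reported here. The table has 39179 genes, of which 17021 were tested, 22144 were not tested for want of data, 3 were marked as low in data, 3 as failed and 8 with a question mark. A shorter sheet of 6953 significant genes with a linear fold by the authors holds the same values. It leaves out 597 of the 7550 genes with a q under 0.05, of which 412 stood under 0.5 FPKM in both groups and the rest were pseudogenes, small RNAs or mitochondrial RNAs. The full table was used.

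Because no value per library was used, no spread between replicates, no error per gene and no new test across libraries could be computed, and the planned model fits on library values were replaced by the branch fixed in advance for tables of group values. Library depth is unknown. The low values were searched for steps of whole reads over 258 olfactory receptor genes, but 28.2% of values lay within 0.1 of a whole multiple of the lower edge, so reads were not recovered. Cufflinks assigns fragments to genes within a locus, and 48.2% of tested genes share their locus with another gene. Values of such genes and of near-identical families (H2, Gbp, Tgtp, Ifit, Oas1, Apol9) depend on that assignment.

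Calls were genes with the authors' q under 0.05. Groups were taken from the labels. The lists, alternatives and naming rule were fixed before the data were examined. For the 28 gene lists, the members called higher, lower or not were counted, also with the authors' p-values adjusted over the list alone. The share of called members was compared with that of all other tested genes by a two-sided Fisher exact test per direction, with Benjamini-Hochberg adjustment over lists and directions. The list median of log2 ratios, bounded at 20 in size, was placed among 10000 random lists of equal size matched on mean FPKM in 20 bins. List members and their relatives were not kept out of any random lists. After the data were seen, a matching on FPKM and transcript length in 10 bins each was added, with the called members counted against the random lists. The permutation p is the share of random lists with at least as many calls, doubled. Counts against lists matched on FPKM alone and on transcript length alone, in 20 bins each, were then added. Transcript lengths and gene coordinates were taken from GENCODE release M21 (GRCm38, the same build). The length of a gene was that of its longest listed transcript, which may exceed the one expressed, and was found for 98.9% of tested genes. Python 3.11.15, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.

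The list tests were tested on simulated data with the 16838 tested genes of known length. Of 200 unchanged lists of 25 genes, 8.5% fell outside the central 95% when matched on expression and length, and all of the lists shifted by -0.8 did. Lists of short genes under a pure length trend fell outside in 91% of cases when matched on expression alone and in 4% when matched on length too. With matching on length alone, 6% of unchanged lists, 3% of lists of short genes and all shifted lists fell outside. The Fisher test passed 5% of unchanged lists and 99% of lists with planted calls. The simulated genes were independent of each other, without a trend with expression, and the simulated calls did not follow length. The simulations thus do not cover lists of genes that change together.

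Named genes were, among called genes of at least 5 FPKM in the higher group and above 0 in both, the 12 largest rises and 10 largest falls, without predicted genes known only by an identifier. To these were added the 3 called genes with a group at 0 and the highest level, up to 4 called members per list with the largest change and at least 1 FPKM in the higher group, for lists with fewer than 2 of these the 2 members of highest level, and 14 fixed genes of the pathway and lineage. Other genes are said to be named after their values were seen. Alternatives were a q under 0.01, a change of at least 2-fold, FPKM floors of 1 and 5, a recomputed q, pseudocounts of 1 and 0.1, and lists without shared or near-identical members.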

Results

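The transcriptome of B16F10.9 cells was measured with and without interferon-gamma (IFN-gamma), the cytokine through which T and NK cells act on tumour cells. B16F10.9 is a pigmented melanoma line of C57BL/6 mouse origin. RNA sequencing was performed on 6 libraries, 3 from untreated cells and 3 from cells kept for 24 h with recombinant mouse IFN-gamma at a labelled dose of 50 µg/ml. The unit of this dose is in doubt, since IFN-gamma is usually given to cultured cells in ng/ml. The comparison addresses which genes differ in expression between treated and untreated melanoma cells. Expression is given as FPKM, fragments scaled to transcript length and to the fragments sequenced. Each group had 1 FPKM value per gene in the authors' deposited table, with no value per library, so no SD or n can be given for any level below. A gene is described as having risen or fallen where the q-value in the authors' deposited table was under 0.05. The read depth of the libraries is unknown. The labels state triplicate seeding and do not say more about how separate the cultures were, so the spread between these libraries may be technical. How that spread entered the q-values is unknown, since the settings of the authors' test are not given.

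After IFN-gamma 3987 genes rose and 3563 fell, and the largest rises were in interferon-inducible genes. The guanylate-binding proteins and immunity-related GTPases, which act against intracellular pathogens, held 5 of the 12 largest rises. Gbp4 went from 0.0106 to 288 FPKM, Igtp from 0.221 to 1388 FPKM, Gbp6 from 0.0291 to 175 FPKM, Gbp11 from 0.0367 to 90.4 FPKM and Gbp2 from 1.4 to 2112 FPKM, all as the authors' values. The other genes among these 12 were Apol6, Zbp1, Oasl2, Cd74, Ifi204, Ifi44 and Apol9a, with log2 ratios between 10.35 and 12.46. All but Gbp2 stood at 0.221 FPKM or less in untreated cells, so that their ratios rest on listed values near 0. Falls were smaller. Outside the small non-coding RNAs, the largest were those of Trnp1 (8.59 to 0.771 FPKM), Gchfr (5.78 to 0.541 FPKM), Spsb4 (18.4 to 1.77 FPKM), Fam171a2 (5.66 to 0.551 FPKM), Fndc4 (5.44 to 0.532 FPKM), Sapcd2 (49.1 to 5.75 FPKM) and Tg (13.5 to 1.85 FPKM). The fall of Fam171a2, which shares its locus with another gene, is less well supported. Its test score by the authors was -0.36 (q = 0.0289 in the authors' deposited table), against -5.39 to -10.98 for the others. Gchfr encodes the feedback regulator of GTP cyclohydrolase, the entry enzyme of tetrahydrobiopterin synthesis. Rpph1, the RNA component of RNase P, fell from 112 to 0.685 FPKM, and the mitochondrial tRNAs mt-Tn and mt-Tc fell from 2069.7 to 168 FPKM and from 1037 to 90.0 FPKM. These are short transcripts, the longest being Rpph1 at 319 nt. As FPKM is scaled to length, few fragments give high values in transcripts this short, so the size of these falls is uncertain. Of 20 tested mitochondrial tRNAs 4 fell, 0 rose and the rest were not called. Of genes with a group at 0, Ly6a, a surface antigen gene, was listed at 0 in untreated cells and at 32.0 FPKM after IFN-gamma, and the class II gene H2-Ab1 at 0 and 29.1 FPKM. The mitochondrial tRNA mt-Tt was listed at 44.6 FPKM in untreated cells and at 0 after IFN-gamma. The authors' test covered 17021 genes, and 1649 of the rises and 1511 of the falls were at least 2-fold. At 4545 of the 7550 called genes the p-value in the authors' deposited table was 5e-05, the smallest it holds, so that calls cannot be ranked by p.

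**Figure D1:**
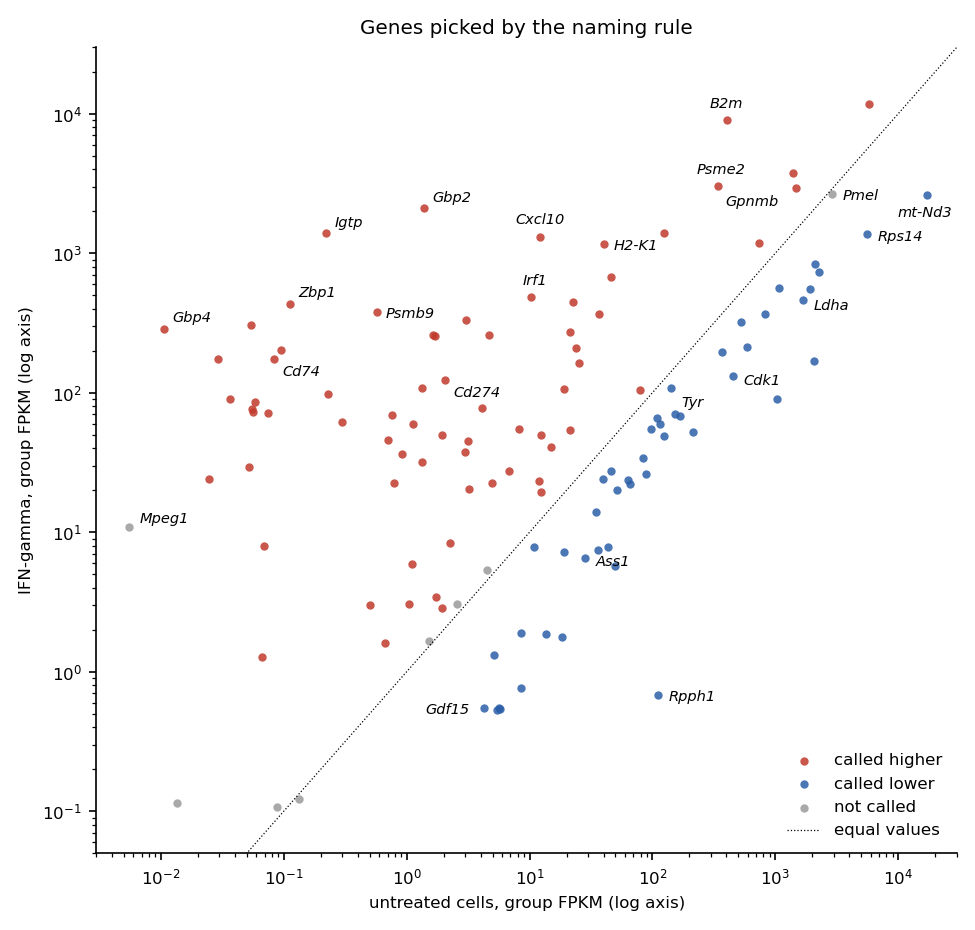
Group FPKM after IFN-gamma (vertical log axis) against untreated cells (horizontal log axis) for the 124 genes of the naming rule that stood above 0 in both groups. Each point is a gene, coloured by the call in the authors' deposited table, and the dotted line marks equal values. B2m lies at 401 and 8967 FPKM and Rpph1 at 112 and 0.685 FPKM.

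The effectors of the IFN-gamma receptor rose almost throughout. Irf1, a transcription factor of the interferon response, rose 47.1-fold, from 10.2 to 482 FPKM, and lies on chromosome 11 (53770014 to 53778374, plus strand, GRCm38). Socs1, the feedback inhibitor of the pathway, rose 65.5-fold, from 0.7002 to 45.8 FPKM, and Stat2 rose from 1.92 to 49.5 FPKM. The receptor kinases rose less, Jak1 from 19.1 to 105 FPKM and Jak2 from 4.94 to 22.6 FPKM. The receptor chains differed from the rest of the list: Ifngr2 fell from 63.8 to 23.7 FPKM, and Ifngr1, at 4.51 and 5.39 FPKM, was not called. Of 16 tested members of the receptor signalling list, 14 rose, 1 fell and 1 was not called, with 14 higher and 1 lower when adjusted over the list alone. The excess of rises over other tested genes had an adjusted p of 1.51e-06 (two-sided Fisher exact test, Benjamini-Hochberg over 28 lists and both directions, used for every list below). This test treats genes as independent. The correlation among the genes of a list cannot be estimated without values per library.

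Genes of MHC class I presentation, which displays peptides to cytotoxic T cells, rose together. B2m, the light chain of class I molecules, rose from 401 to 8967 FPKM (22.3-fold). It lies on chromosome 2 (122147686 to 122153083, plus strand, GRCm38). The heavy chain genes H2-K1 and H2-D1 rose from 40.0 to 1168 FPKM and from 124 to 1391 FPKM, and H2-T23 from 1.65 to 259.97 FPKM. H2-K1 and H2-D1 are close copies of each other and of the H2-Q genes, and fragments could be divided between them, so the single values are uncertain. The peptide transporter genes Tap1 and Tap2 rose from 3.07 to 331 FPKM and from 1.70 to 255 FPKM, and the class I transactivator Nlrc5 from 1.32 to 108 FPKM. Of 20 tested members 16 rose, 0 fell and 4 were not called, and 16 were higher when adjusted over the list alone (adjusted Fisher exact p = 1.62e-06). The general folding factors Calr, Canx and Pdia3 and the gene H2-T24, named after their values were seen, were the members without a call. The genes of the immunoproteasome, which trims antigens for class I, and of a proteasome activator (Psme1 and Psme2) showed the same direction. Psmb9 rose from 0.578 to 378 FPKM, Psmb10 from 22.7 to 450.1 FPKM, Psme1 from 45.7 to 679.6 FPKM and Psme2 from 341 to 3017 FPKM. Of 5 tested members 4 rose, 0 fell and 1 was not called, while all 5 were higher when adjusted over the list alone. The excess had an adjusted p of 0.0447, and of 0.0777 over genes with at least 1 FPKM in either group. Against random lists matched on expression, a count chosen after seeing the data, the adjusted permutation p was 0.0747. The member without a call was Psmb8, named after its values were seen, listed at 0.00644 and 11.8 FPKM with a q of 0.0565 in the authors' deposited table.

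Members of the constitutive proteasome went both ways. Of 26 tested members 9 rose, 8 fell and 9 were not called, with 9 higher and 9 lower when adjusted over the list alone (adjusted Fisher exact p = 0.384 for rises and 0.44 for falls). The largest changes in size were falls: Psmb3 from 586 to 214 FPKM, Psma7 from 820.5 to 367 FPKM, Psmb4 from 1079.6 to 560.2 FPKM and Psmb6 from 367 to 195 FPKM. Psmb6 encodes the catalytic subunit that Psmb9 replaces in the immunoproteasome. The largest rises, named after their values were seen, were those of Psma5 (97.51 to 179.9 FPKM) and Psmb2 (116 to 179 FPKM). The list median log2 ratio of 0.01 stood at the 97.4th percentile of random lists matched on expression. It stood at the 98.4th percentile of lists matched on expression and transcript length, whose median was -0.36, a comparison chosen after seeing the data.

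Class II genes, normally the property of antigen-presenting cells, included some of the largest rises. Cd74, the invariant chain, rose from 0.0830 to 173 FPKM. H2-DMa and H2-DMb1, which encode the peptide-loading factor of class II, rose from 0.298 to 61.6 FPKM and from 0.920 to 36.4 FPKM. H2-Ab1 was called from its listed value of 0. The fall was that of Ifi30 (40.2 to 26.7 FPKM), named after its values were seen. Of 10 tested members 4 rose, 1 fell and 5 were not called, with 4 higher and 1 lower when adjusted over the list alone. The excess of rises did not pass the test (adjusted Fisher exact p = 0.466). It did so where calls also needed to change at least 2-fold (adjusted Fisher exact p = 0.0492). Among the members without a call, named after their values were seen, H2-Aa was listed at 0.0129 and 38.2 FPKM, H2-Eb1 at 0.0211 and 57.4 FPKM, and Ciita, the class II transactivator, at 0.00693 and 12.6 FPKM, with q-values from 0.243 to 0.373 in the authors' deposited table.

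The IFN-inducible GTPases held the highest list median of all, a log2 ratio of 11.69. The median was 9.40 with a pseudocount of 0.1 and 7.45 with a pseudocount of 1, the highest of the 25 lists under both. Of 20 tested members 12 rose, 0 fell and 8 were not called, and 13 were higher when adjusted over the list alone (adjusted Fisher exact p = 0.00345). The genes Gbp4, Gbp6 and Gbp11 lie side by side on chromosome 5 between 105115767 and 105346472 (GRCm38), Gbp2 lies on chromosome 3, and Igtp on chromosome 11. The Gbp and Tgtp genes are families of near-identical copies, so their single values are uncertain. Members without a call, named after their values were seen, included Iigp1 at 0.0327 and 672 FPKM, Tgtp2 at 0.0399 and 660.1 FPKM, and Gbp10 at 0.00381 and 121 FPKM. Their q-values in the authors' deposited table were 0.103, 0.124 and 0.347. The antiviral interferon-stimulated genes rose almost without exception. The nucleic acid sensor Zbp1 rose from 0.112 to 434 FPKM, Oasl2 from 0.0949 to 202 FPKM, Ifi44 from 0.0553 to 77.0 FPKM and Oas3, a synthetase that activates RNase L, from 0.0527 to 29.3 FPKM. Of 40 tested members 38 rose, 1 fell and 1 was not called, with 38 higher and 1 lower when adjusted over the list alone (adjusted Fisher exact p = 2.54e-20). The fall, named after its values were seen, was that of Ifitm2 (168 to 135 FPKM), and Oas2, at 0.0137 and 27.2 FPKM, was not called.

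Chemokines and cytokines rose more often than other genes, by amounts that differed widely. Cxcl10, which attracts T cells through Cxcr3, rose 107.6-fold from 12.2 to 1312 FPKM, and Ccl5 rose 12.8-fold from 21.3 to 272 FPKM. Il18bp, a soluble inhibitor of interleukin-18, rose from 0.761 to 69.4 FPKM and Csf1 from 3.19 to 20.3 FPKM. The smallest rises of the list, named after their values were seen, were those of Tgfb1 (1.74 to 2.59 FPKM) and Tgfb2 (1.86 to 2.90 FPKM). Of 16 tested members 10 rose, 1 fell and 5 were not called, with 12 higher and 1 lower when adjusted over the list alone (adjusted Fisher exact p = 0.00591). The adjusted p was 0.0861 with calls at q under 0.01 and 0.0876 over genes of at least 5 FPKM. The fall was that of Vegfa, an angiogenic factor named after its values were seen, from 29.4 to 8.47 FPKM.

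Among ligands seen by T and NK cells, Cd274, which encodes the checkpoint ligand PD-L1, rose 59.7-fold from 2.05 to 122 FPKM. It lies on chromosome 19 (29367455 to 29388095, plus strand, GRCm38). Tnfsf10, the death ligand TRAIL, rose from 0.0698 to 7.94 FPKM, Tnfrsf14 from 0.790 to 22.7 FPKM and Lgals9 from 25.1 to 163 FPKM. Of 21 tested members 8 rose, 4 fell and 9 were not called, with 9 higher and 4 lower when adjusted over the list alone. The excess of rises had an adjusted p of 0.299, against 0.0404 over genes of at least 1 FPKM in either group. Complement genes included large rises. Serping1, the inhibitor of C1, rose from 0.0248 to 24.0 FPKM, C4b from 0.231 to 97.9 FPKM, C1ra from 4.12 to 77.3 FPKM and C2 from 36.9 to 364 FPKM. Of 9 tested members 5 rose, 1 fell and 3 were not called, with 6 higher and 1 lower when adjusted over the list alone (adjusted Fisher exact p = 0.111, or 0.00476 with a change of at least 2-fold). Metabolic targets of interferon went both ways. Apol9a and Apol9b, near-identical genes whose values are uncertain, rose from 0.0560 to 73.3 FPKM and from 0.0753 to 71.6 FPKM. Ido1, which degrades tryptophan, rose from 0.502 to 3.01 FPKM, and Ass1, which makes the precursor of arginine from citrulline, fell from 28.5 to 6.57 FPKM. Of 13 tested members 5 rose, 3 fell and 5 were not called, also when adjusted over the list alone (adjusted Fisher exact p = 0.429 for rises).

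Genes of the cell death machinery rose more often than other genes. Mlkl, the executor of necroptosis, rose from 24.0 to 208 FPKM, the pore-forming Gsdmd from 3.01 to 37.7 FPKM, and the inflammatory caspases Casp4 and Casp12 from 3.14 to 45.1 FPKM and from 1.12 to 59.7 FPKM. Of 25 tested members 16 rose, 3 fell and 6 were not called, with 16 higher and 3 lower when adjusted over the list alone (adjusted Fisher exact p = 0.000166). The falls included Bax (269.7 to 79.2 FPKM) and Bbc3 (13.5 to 6.34 FPKM), both named after their values were seen. Bax and Bbc3 act in the mitochondrial pathway of apoptosis and are targets of p53. Among CDK inhibitors and p53 targets 2 of 15 tested members rose, 7 fell and 6 were not called, also when adjusted over the list alone (adjusted Fisher exact p = 0.0714 for falls). Gdf15 fell from 4.26 to 0.552 FPKM, Ei24 from 125 to 48.8 FPKM, the CDK inhibitor Cdkn1a from 166 to 68.4 FPKM and Ccng1 from 115 to 59.97 FPKM.

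Cell cycle and DNA replication genes fell together. Cyclin E2 (Ccne2) fell from 43.2 to 7.87 FPKM, the thymidylate synthase gene Tyms from 212 to 51.9 FPKM, the mitotic kinase gene Cdk1 from 451 to 131 FPKM and Cdc20, an activator of the anaphase-promoting complex, from 89.4 to 26.2 FPKM. The proliferation marker Mki67 fell from 10.97 to 7.78 FPKM, a log2 ratio of -0.50. With the length trend described below taken out, a step chosen after seeing the data, its ratio was -1.17. Of 38 tested members 33 fell, 2 rose and 3 were not called, with 33 lower and 2 higher when adjusted over the list alone (adjusted Fisher exact p = 1.57e-16). The rises, named after their values were seen, were those of the cyclin D2 gene Ccnd2 (82.3 to 142 FPKM) and Cdk6 (0.602 to 1.35 FPKM). The list median log2 ratio was -0.95, below that of every one of 10000 random lists matched on expression.

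Genes of the melanocyte list went in different directions, with more rises than falls. Mitf, the master regulator of the melanocyte lineage, rose 1.33-fold from 78.7 to 105 FPKM. Tyr, the rate-limiting enzyme of melanin synthesis, fell from 142 to 107 FPKM, and Pmel, at 2871 and 2669.5 FPKM, was not called. With the length trend described below taken out, a step chosen after seeing the data, the log2 ratio of Mitf went from 0.41 to 0.17. That of Tyr went from -0.40 to -0.86. The melanosomal glycoprotein gene Gpnmb rose from 1469.95 to 2942 FPKM and Slc24a4 from 1.75 to 3.46 FPKM. Further rises, named after their values were seen, included Sox10 (112 to 195 FPKM) and Tyrp1 (2337 to 4045 FPKM). Mlana (1906 to 2649 FPKM) and Pax3 (22.4 to 30.1 FPKM), also named after their values were seen, rose too. Trpm1 fell from 153 to 70.2 FPKM and Melk, a kinase of dividing cells, from 19.0 to 7.26 FPKM. Of 24 tested members 9 rose, 3 fell and 12 were not called, also when adjusted over the list alone (adjusted Fisher exact p = 0.334 for rises). Markers of dedifferentiated melanoma and neural crest rose where they changed. The fibronectin gene Fn1 rose from 1.34 to 32.1 FPKM, Jun from 12.3 to 49.5 FPKM, the receptor kinase gene Axl from 2.24 to 8.43 FPKM and Snai2 from 1.05 to 3.04 FPKM. Of 15 tested members 9 rose, 0 fell and 6 were not called, with 10 higher and 1 lower when adjusted over the list alone (adjusted Fisher exact p = 0.0121). The transcripts of this list are long, with a median of 4265 nt. Against random lists matched on expression and transcript length, a comparison chosen after seeing the data, 9 rises stood against a mean of 4.75 (adjusted permutation p = 0.142). The adjusted permutation p was 0.313 with matching on length alone and 0.0140 on expression alone. The list median log2 ratio of 0.9985 nonetheless stood at the 99.59th percentile of lists matched on expression and length, whose median was 0.26. With matching on length alone it stood at the 99.93th percentile.

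**Figure D2:**
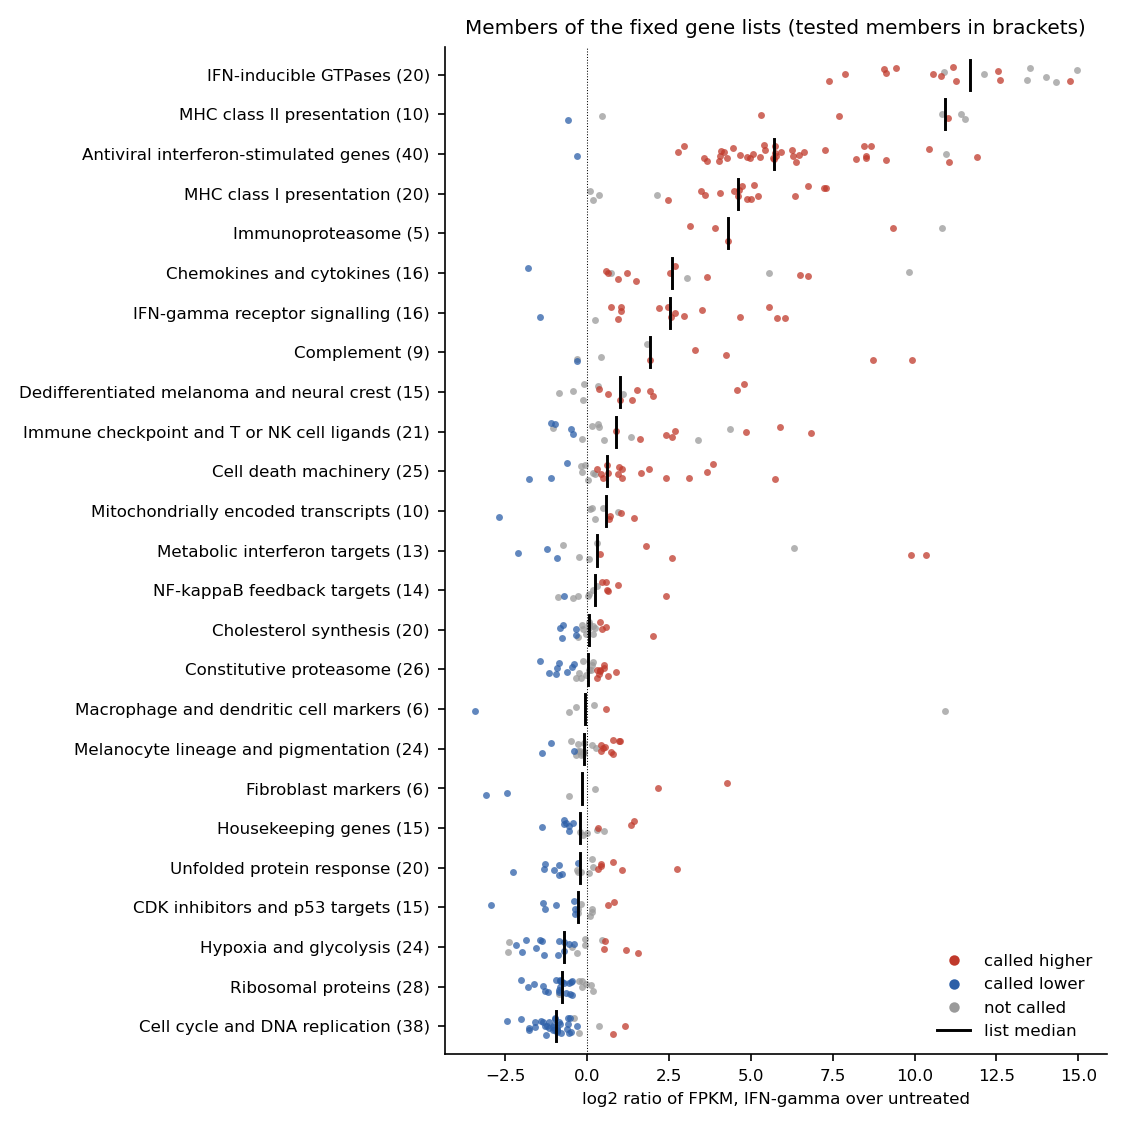
Log2 ratio of group FPKM, IFN-gamma over untreated (horizontal axis), for the tested members of the 25 lists with at least 5 tested members, ordered by list median. Points are genes, coloured by the call in the authors' deposited table, black bars are list medians, and 4 members with a group at 0 are not drawn. Medians run from 11.69 for the IFN-inducible GTPases to -0.95 for the cell cycle list.

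Genes of hypoxia and glycolysis fell more often than other genes. The lactate dehydrogenase gene Ldha fell from 1689 to 462 FPKM, the carbonic anhydrase gene Car9 from 8.58 to 1.89 FPKM, the lactate exporter gene Slc16a3 from 5.19 to 1.32 FPKM and Bnip3 from 65.8 to 22.3 FPKM. Of 24 tested members 13 fell, 4 rose and 7 were not called, with 15 lower and 4 higher when adjusted over the list alone (adjusted Fisher exact p = 0.00277). The rises, named after their values were seen, included Hk2 (11.3 to 33.1 FPKM) and P4ha1 (11.5 to 26.1 FPKM). Against random lists matched on expression and length, a comparison chosen after seeing the data, 13 falls stood against a mean of 7.51 (adjusted permutation p = 0.139). The adjusted permutation p was 0.248 with matching on expression alone and 0.0174 on length alone. The unfolded protein response went both ways: of 20 tested members 6 rose, 8 fell and 6 were not called, with 6 higher and 9 lower when adjusted over the list alone (adjusted Fisher exact p = 0.702 for rises and 0.14 for falls). The stress factor gene Atf3 rose from 8.22 to 55.3 FPKM, while Chac1, Trib3 and Herpud1 fell from 36.1 to 7.43 FPKM, from 34.9 to 13.9 FPKM and from 83.3 to 33.9 FPKM. In cholesterol synthesis 4 of 20 tested members rose, 5 fell and 11 were not called, also when adjusted over the list alone (adjusted Fisher exact p = 1 for rises and 0.84 for falls). Hsd17b7 rose from 6.86 to 27.5 FPKM, and Insig1, Mvk and Cyp51 fell to 55.4, 27.3 and 65.5 FPKM. Among NF-kappaB feedback targets 6 of 14 tested members rose, 1 fell and 7 were not called, also when adjusted over the list alone (adjusted Fisher exact p = 0.279 for rises). Bcl3 rose from 1.10 to 5.89 FPKM, Tnip1 from 12.02 to 23.3 FPKM and Nfkb1 from 12.3 to 19.3 FPKM, and Nfkbib fell from 39.5 to 24.2 FPKM.

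Ribosomal protein genes fell more often than other genes. Rps14 fell from 5559 to 1362 FPKM, Rpl11 from 1919.6 to 554 FPKM, Rps3 from 2244 to 736 FPKM and Rpl18 from 2095 to 831 FPKM. Of 28 tested members 21 fell, 0 rose and 7 were not called, with 21 lower when adjusted over the list alone (adjusted Fisher exact p = 2.45e-08). These are short transcripts, with a median of 1124 nt, and direction followed transcript length over all protein-coding genes of at least 1 FPKM. Up to 600 nt the median log2 ratio was -0.62, with 4.91% of genes higher and 39.9% lower. Over 10000 nt it was 0.75, with 62.9% higher and 5.24% lower. With this trend taken out, the log2 ratio of Rps14 was -1.42 and that of Rpl18 -0.73. Against random lists matched on expression and length, 21 ribosomal falls stood against a mean of 17.0 (adjusted permutation p = 0.555). Random lists could draw the ribosomal members themselves and other ribosomal protein genes, which makes an excess harder to see. With matching on expression alone the mean was 14.2 (adjusted permutation p = 0.0997), and the list median stood at the 4.475th percentile. With matching on length alone the mean was 7.82 (adjusted permutation p = 0.00187). The 33 cell cycle falls stood against a mean of 11.3 with matching on expression and length (adjusted permutation p = 0.00187). Before adjustment the permutation p was 0.0002, the smallest that 10000 lists can give. Housekeeping genes, which watch RNA quality here, were not level. Polr2a rose from 15.0 to 40.7 FPKM, and Pgk1 fell from 522 to 319 FPKM. Of 15 tested members 3 rose, 7 fell and 5 were not called, also when adjusted over the list alone (adjusted Fisher exact p = 1 for rises and 0.0714 for falls). Of 10 tested mitochondrially encoded transcripts 4 rose, 1 fell and 5 were not called, also when adjusted over the list alone (adjusted Fisher exact p = 0.466 for rises and 0.87 for falls). The rises included mt-Nd4 (1395 to 3759.6 FPKM), mt-Co1 (5789 to 11770.1 FPKM) and mt-Nd5 (736 to 1182 FPKM). The fall was that of mt-Nd3 (17088 to 2629 FPKM), whose transcript has 348 nt. The transcripts of this list are short, with a median of 997.5 nt, yet its median log2 ratio of 0.57 stood at the 99.9th percentile of lists matched on expression and length, whose median was -0.62.

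**Figure D3:**
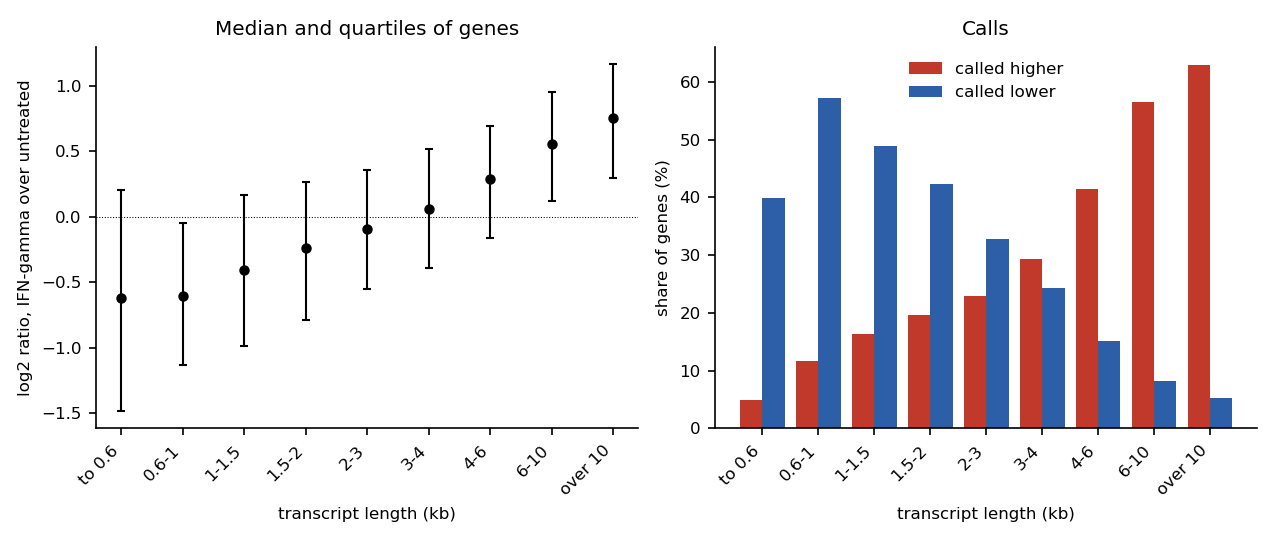
Protein-coding genes of at least 1 FPKM in either group by annotated transcript length (horizontal axis, kb). The left panel shows the median log2 ratio, IFN-gamma over untreated, with bars from the lower to the upper quartile of genes, and the right panel the share of genes called higher or lower in the authors' deposited table. The median runs from -0.62 in the shortest class to 0.75 in the longest.

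Markers of other cell types were low, and few of them reached the authors' test. Of T and NK cell markers 2 were tested and neither was called, in the table or adjusted over the list alone, with Lck at 1.51 and 1.67 FPKM and Cd3d at 0.0877 and 0.108 FPKM (adjusted Fisher exact p = 1). Of macrophage and dendritic cell markers 6 were tested, 1 rose, 1 fell and 4 were not called, also when adjusted over the list alone (adjusted Fisher exact p = 1). Cd68 rose from 1.92 to 2.85 FPKM, and Mpeg1, at 0.00554 and 10.9 FPKM, was not called. Of B cell markers 2 were tested, of which Cd79a rose from 0.661 to 1.60 FPKM and Cd79b, at 0.0136 and 0.114 FPKM, was not called, and 1 was higher when adjusted over the list alone (adjusted Fisher exact p = 0.681). Of 6 tested fibroblast markers 2 rose, 2 fell and 2 were not called, also when adjusted over the list alone (adjusted Fisher exact p = 0.84). Lum rose from 0.0664 to 1.29 FPKM, and Postn, at 2.57 and 3.07 FPKM, was not called. Of endothelial and epithelial markers only Pecam1 was tested, at 0.132 and 0.122 FPKM, and it was not called, also when adjusted over the list alone (adjusted Fisher exact p = 1).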

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

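The genes in this paragraph lie outside the tested set and stood higher after IFN-gamma than in untreated cells. The mitochondrial genes mt-Atp8, mt-Atp6 and mt-Co3, which share a locus, were marked as low in data. They were listed at 0 FPKM in untreated cells and at 64502.8, 23376 and 14062.7 FPKM after IFN-gamma. As every mitochondrion transcribes these genes, the value of 0 is read as a failed estimate and no ratio is given. Nav1 and the predicted gene Gm4793 had a failed test, with 6.11 and 11.8 FPKM for Nav1 and 1.06 and 1.84 FPKM for Gm4793. No explanation was tested for these values.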

How the results depend on the processing

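No paired analysis was possible because the table holds 1 value per group. For the same reason the planned limma fits with their pseudocounts, filters and scalings, the fits without each replicate, camera, fry, the count models and other splits of the samples were not run. The matchings on expression, length or both for counts of calls, the protein-coding and single-gene-locus subsets and the removal of the length trend were chosen after seeing the data. A change of at least 2-fold left 3160 of 7550 called genes, 1649 higher and 1511 lower, and genes alone in their locus gave 4738, 2374 higher and 2364 lower, since both keep fewer genes. The other 6 settings gave between 5587 and 7445 called genes. The 7445 belongs to the setting with the length trend removed. That step kept the call of every called gene with a length and could alter only its direction and size. With the trend removed, 1343 rises and 1199 falls among these genes were at least 2-fold, against 1649 and 1511 among all called genes without that step. The share of rises among calls ran from 50.1% to 53.6% over all settings. With the length trend removed, 190 rises and 112 falls of 7445 called genes with a length changed sign, and the 124 named genes above 0 in both groups kept theirs where called. Of lists, 8 had an excess of rises and 3 of falls. With random lists matched on expression and length 7 and 1 were left by count of calls, the ribosomal, hypoxia and dedifferentiation lists being lost. The hypoxia and dedifferentiation medians stayed outside the central 95% of these lists (0.09th and 99.59th percentiles), and the ribosomal median did not. Matching on expression alone left 7 and 1, without the ribosomal, hypoxia and immunoproteasome lists. Matching on length alone left 7 and 3, without the dedifferentiation list. The 9 alternatives kept the excess for the signalling, class I, GTPase, antiviral, cell death and cell cycle lists. The ribosomal excess also ended with a change of at least 2-fold (adjusted Fisher exact p = 0.125). A change of at least 2-fold added the class II, complement and checkpoint lists. Of 25 lists with at least 5 tested members, 14 had a median outside the central 95% of random lists, and 13 to 15 did under the alternatives. The immunoproteasome excess ended over genes of at least 1 or 5 FPKM (adjusted Fisher exact p = 0.0777 and 0.0901). Of the 124 named genes above 0 in both groups, 40 moved by over 1.5 times in ratio with a pseudocount of 1 and 17 with 0.1. With the length trend taken out 14 moved by over 1.5 times or changed sign. Those that changed sign were Pmel and Postn, not called, which moved by less than 1.5 times. Depth, unknown here, limits what the values near 0 can show.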

Other observations

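Gene families not fixed in advance were compared by symbol stem, over 195 stems with at least 8 tested protein-coding members (two-sided Fisher exact tests, Benjamini-Hochberg over stems and directions, stems chosen after seeing the data). The Parp family of ADP-ribosyltransferases was called higher more often than other genes: 9 of 12 members were higher and 2 lower (adjusted Fisher exact p = 0.0286). Parp14 rose from 0.297 to 87.9 FPKM, Parp11 from 5.47 to 83.3 FPKM, Parp10 from 12.1 to 143 FPKM and Parp3 from 25.5 to 116 FPKM. Parp1, which acts in DNA repair, fell from 37.6 to 25.9 FPKM. The family median lay above all 1000 random lists matched on expression and length, and 3 members also belong to the antiviral list. The Akap scaffolds (10 of 12 higher, adjusted Fisher exact p = 0.00583), the Dock exchange factors and the Chd remodellers (8 of 10 each, adjusted Fisher exact p = 0.0286) also had more higher calls than other genes. Their transcripts are long, with medians from 6099 to 8638 nt, and their medians stood at the 93.6th, 98th and 93.9th percentiles.

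The Timm genes and genes of mitochondrial ribosomes were called lower more often than other genes. Of 13 Timm genes, which encode the import machinery of the inner membrane, 10 fell and 0 rose (adjusted Fisher exact p = 0.00571). Timm8b fell from 531 to 146 FPKM and Timm50 from 120 to 35.8 FPKM, and the family median lay at the 0.8th percentile of matched lists. Of 9 Tomm genes, which encode import factors of the outer membrane, 6 fell and 0 rose, which did not pass the test (adjusted Fisher exact p = 0.116). Of 29 Mrps genes 20 fell and 1 rose (adjusted Fisher exact p = 5.25e-05, 2.5th percentile), and of 47 Mrpl genes 24 fell, 1 rose and 22 were not called (adjusted Fisher exact p = 0.00571, 21st percentile). The Mrpl median thus lay well inside the range of lists of like expression and length. Of 10 genes with the Mcm stem, 7 of which stand in the cell cycle list, 8 fell and 1 rose (adjusted Fisher exact p = 0.0117). The falls included Mcm2 from 189 to 62.6 FPKM and Mcm5 from 111 to 37.1 FPKM. The rise was that of Mcm3ap (5.03 to 8.39 FPKM), grouped here by its symbol alone. All 8 NADH dehydrogenase genes called in the Ndufb family fell, of 10 tested (adjusted Fisher exact p = 0.0117, 6.5th percentile).

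In the 3 paragraphs that follow, the tests on the lists, on values near 0 and on macrophage genes were chosen after the result was seen. Falls were concentrated in short and rises in long transcripts, with a Spearman rho of 0.38 between length and log2 ratio across 11014 protein-coding genes, which are not independent replicates. Assignment of fragments among isoforms as the cause is argued against by genes with 1 listed transcript, where rho was 0.384. The trend as the whole cause of the cell cycle and hypoxia falls is argued against too, since their medians of -0.95 and -0.70 stood at percentile 0 and at the 0.09th percentile of lists matched on expression and length, whose own medians were -0.000443 and -0.05, although the count of hypoxia falls missed the threshold (permutation p = 0.0224 before adjustment). For the ribosomal median of -0.78 a trend with the longest listed length alone is argued against by the 0.89th percentile of lists matched on it. The expressed transcripts may be shorter (Rps3 was matched at 3183 nt), so this cannot decide on their own length. A trend shared by genes of like expression and length is a candidate explanation, at the 11.1th percentile of lists with a median of -0.56 (4.475th with expression alone). As those lists could draw ribosomal protein genes too, they cannot separate such a trend from a fall of this gene family. A length-dependent difference between the libraries of the groups, such as in RNA quality or fragment size, and an effect of IFN-gamma cannot be told apart: rho was 0.0985 among 378 lincRNA and processed-transcript genes (bootstrap interval over genes -0.00196 to 0.198), a span on both sides of the bound of 0.1, and each group has 1 value.

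Some of the strongest rises carried no call. Of 114 genes above 0 in untreated cells with at least 5 FPKM after IFN-gamma and a log2 ratio of at least 5, 90 were called. Below 0.05 FPKM in untreated cells 11 of 33 were called and at or above it 79 of 81 (two-sided Fisher exact p = 2.3e-13). This cut was set with the values known and lies just above Tgtp2 (0.0399 FPKM), the highest protein-coding gene without a call. The p therefore describes the split and does not test the explanation. Gbp4 was called from 0.0106 FPKM, while Iigp1 at 0.0327 FPKM was not. Outside these 114, of genes listed at 0 in untreated cells 7 of 77 were called, and 3 of 5 protein-coding ones. An untreated value near 0 stays a candidate explanation, not decided here, for the missing calls on Iigp1, Tgtp2, Gbp10, H2-Aa, H2-Eb1, Ciita and Psmb8. Sharing of a locus stays open, with 39 of 52 called in loci of several genes and 51 of 62 in loci of 1 gene (two-sided Fisher exact p = 0.366). No biological explanation was tested.

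Class II genes and Mpeg1 are typical of macrophages and dendritic cells, and such cells in the treated cultures could bring them. The 8 abundant macrophage genes C1qa, C1qb, C1qc, Tyrobp, Fcer1g, Lyz2, Csf1r and Ptprc had a median rise of -0.00319 FPKM, but 6 of them were not tested, and C1qc and Tyrobp were listed at 0 in both groups, which may be failed estimates. Such cells as the source are argued against by the 5 genes above 0 in both groups, with a median rise of -0.0869 FPKM, and by the tested Lyz2 (1.65 to 1.30 FPKM, 0.749% of Cd74) and Fcer1g (0.715 to 0.484 FPKM). Induction of class II genes in the melanoma cells by IFN-gamma is left as a hypothesis from these data.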
